A study of Mus musculus with 4 samples.

How the data were processed

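Droplet single-cell RNA libraries were used from 4 samples of 20-month-old male C57BL/6J mice with a tibial fracture, 2 treated with an adenosine-containing microgel and 2 with a control microgel, harvested 7 days after treatment. Per the labels, viable cells were sorted by propidium iodide after lysis of red blood cells, and libraries were prepared with the 3' v2 kit and sequenced on an MGISEQ-2000. The labels give bone marrow as the tissue and describe callus cells; the text below calls the samples by their treatment and number. Per the labels, the authors ran Cell Ranger 7.0.0 and bcl2fastq with genome build mm10; the annotation release and the handling of intronic reads are not given in the sources used here. The deposited matrices hold raw UMI counts per gene and cell barcode, in whole numbers, for barcodes that the authors called as cells (lowest total 500 UMIs). They list 32285 genes, of which 32235 have an identifier in GENCODE M21.

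The 4 libraries held 9949 (control 1), 6753 (control 2), 9402 (adenosine 1) and 9170 (adenosine 2) barcodes with 58453640, 32277757, 59503381 and 68117846 UMIs. Cells with fewer than 200 genes or a mitochondrial share of 10% or more were removed (1576 in all). Doublet scores were computed per library with Scrublet as in scanpy 1.11.5 (Python 3.11.15), and the cells with the highest scores were removed at a rate of 0.8% per 1000 barcodes (2367 in all), since the automatic threshold marked 0.0296% of control 2 and 0.0319% of adenosine 1. This left 8693, 6283, 8219 and 8136 cells with a median of 3766, 2992, 3477 and 4745.5 UMIs. The limit of 3 counts used below equals 0.0599, 0.102, 0.0575 and 0.0516 CPM (counts scaled by the UMI total of the library or class) in the sum of all cells.

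Cells were scaled to 10000 UMIs, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2) gave 38 clusters. A cluster was named from 20 marker lists by the mean log2 CPM of each list over the mean of all clusters (pseudocount 10 CPM), needing at least 3 markers raised by 1 log2 unit, a margin of 0.25 over the next list and 20 cells; 35 clusters were named, and 89 cells stayed unnamed. Clusters were not corrected for library, so some were filled mainly by 1 library. Shares of cells carry 95% Wilson intervals.

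The library was the unit of replication. Numbers of cells per class were compared with the edgeR 4.0.16 quasi-likelihood test with total cells as library size. For genes, UMI counts were summed per library over all cells and over each class with at least 50 cells in every library (neutrophils, monocyte-macrophages, B cells and dendritic cells), filtered with filterByExpr, scaled by TMM and tested with the edgeR quasi-likelihood test in R 4.3.3. T or NK cells were not tested within their class, since control 2 held 46. All p-values are two-sided and were adjusted by Benjamini and Hochberg within a comparison, with a threshold of 0.05. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at the preset correlation of 0.01 between genes; members were also adjusted over their list alone. The difference of the change between neutrophils and monocyte-macrophages was tested with the library as a block.

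The 24 lists covered adenosine receptors and handling, the cAMP response, the dissociation and stress response, inflammatory cytokines and mediators, alternative macrophage activation, the interferon response, MHC class II presentation, osteoblast and mineralization, cartilage, osteoclast, extracellular matrix and fibrosis, angiogenesis and endothelium, hypoxia and glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, cell cycle, neutrophil primary granules, secondary and tertiary granules, mature neutrophil, senescence and secretory phenotype, B lymphopoiesis, hemoglobin and erythroid, and skeletal muscle; 5 of their symbols are absent from the deposited gene lists. Lists, markers, tests, thresholds and the rule for naming genes were fixed before the data were examined. By that rule, genes past the threshold would be named by fold change; as no gene passed, up to 4 genes with the lowest unadjusted p in each direction and at least 20 CPM in the higher group are given, leaving out predicted genes and immunoglobulin or T cell receptor segments, with up to 4 members per described list and the adenosine receptors, Nt5e, Entpd1, Ada and Adk.

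The procedure was tested on simulated data with 2 libraries per group. At a coefficient of variation of 0.1 it found 100% of genes changed 4-fold and 81% to 100% of genes changed 2-fold; at 0.4, nearer to the observed 0.285 to 0.494, it found 15% to 32% and 0% to 4%. The test on the 13 classes of cells found a 4-fold change, set in B cells only, in 100 of 100 draws at 0.1, 35 at 0.4 and 0 at 1.08, the common coefficient of variation seen between libraries. In these it called another class in 35, 11 and 6 draws, and without a change it made a call in 10, 7 and 3 of 100 draws.

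Alternatives covered DESeq2 1.42.0, DESeq2-type size factors, library size only, no filter on low counts, stricter cells (at least 500 genes and under 5% mitochondrial), all deposited barcodes, no doublet removal, Leiden resolutions of 0.5 and 2, classes by marker score per cell, TMM factors or the total outside the most abundant class for cell numbers, camera with an estimated correlation, fry, each library left out in turn and the replicate number as a block. Counts thinned to the lowest library total were added after the data were seen. The files share only a number between the groups, which does not show that libraries 1 or 2 were handled together, so no pairing was used in the tests reported. Barcodes and gene lists were used as names only.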

Results

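Single-cell libraries of fracture calluses from 20-month-old male mice, harvested 7 days after an adenosine-containing or an empty (control) microgel, held mostly myeloid cells. Across the 4 libraries, 2 per group, 31331 cells were kept, and neutrophils made up 67.5% and 76.7% of the cells of control 1 and control 2 and 66.7% and 52.5% of those of adenosine 1 and adenosine 2. Monocyte-macrophages followed with 16.8%, 16.5%, 11.9% and 15.0%. Values per library are given below in the order control 1, control 2, adenosine 1, adenosine 2. The labels do not say whether the 2 libraries of a group came from separate animals, so the p-values measure only the spread between libraries.

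T or NK cells, named from genes such as the T cell receptor subunits Cd3e and Trac, made up 2.37% (95% Wilson interval 2.07 to 2.71), 0.732% (0.549 to 0.975), 3.67% (3.29 to 4.10) and 15.0% (14.2 to 15.8) of cells. B cells accounted for 4.41%, 1.29%, 4.06% and 8.46%, granulocyte-monocyte progenitors, which carry the early granule proteases Elane and Prtn3, for 4.24%, 0.302%, 6.92% and 5.47%, and dendritic cells for 2.54%, 3.58%, 2.24% and 1.92%. Neutrophils, monocyte-macrophages and dendritic cells were lower in both adenosine libraries than in both control libraries, and T or NK cells, granulocyte-monocyte progenitors and basophils or mast cells were higher. With classes set by marker score per cell, the log2 ratio was 0.19 for neutrophils and -2.20 for basophils or mast cells. By chance, 2 libraries lie apart from 2 others in either direction in 33.3% of classes. Osteoclasts, the bone-resorbing cells, numbered 2, 38, 11 and 5, and mesenchymal cells or fibroblasts 3, 12, 30 and 1. Erythroid cells numbered 21, 0, 102 and 2; a count of 0 in control 2 allows up to 0.0477% at a limit of 3 counts. Red blood cell lysis and the sort for viable cells by propidium iodide can set the erythroid share.

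No class passed the edgeR test on cell numbers, in which 0 of 13 classes also had an unadjusted p under 0.05. By log2 ratio, the largest group difference in a class with a mean above 1% in either group was that of T or NK cells, with means of 9.33% (SD 8.005) in adenosine and 1.55% (SD 1.16) in control libraries, a log2 ratio of 2.59 (SE 1.24) and adjusted p = 0.770. In percentage points neutrophils differed most, with means of 59.6% (SD 10.0) and 72.1% (SD 6.46), log2 -0.27 (SE 0.68) and adjusted p = 0.770; by marker score per cell the ratio was 0.19. Granulocyte-monocyte progenitors had means of 6.20% (SD 1.03) and 2.27% (SD 2.79), log2 1.44 (SE 1.47) and adjusted p = 0.770. Control 2 carried much of this ratio, at 0.302% against 4.24% in control 1. The test draws on a spread shared by the 13 classes, rare ones included, so an SE does not give the spread of its own class. Monocyte-macrophages also had an SE of 0.68, though their shares in the control libraries were 16.8% and 16.5%. For abundant classes the adjusted p thus does not rest on their own spread alone. In simulated data with every class at the common spread seen between libraries (coefficient of variation 1.08), the test found a 4-fold change in 0 of 100 draws. Only B cells were changed in these draws, so they do not give the power for a class of smaller spread. The exact permutation p of 2 libraries against 2 cannot go under 0.333. The intervals given for shares cover counting error only.

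**Figure D1:**
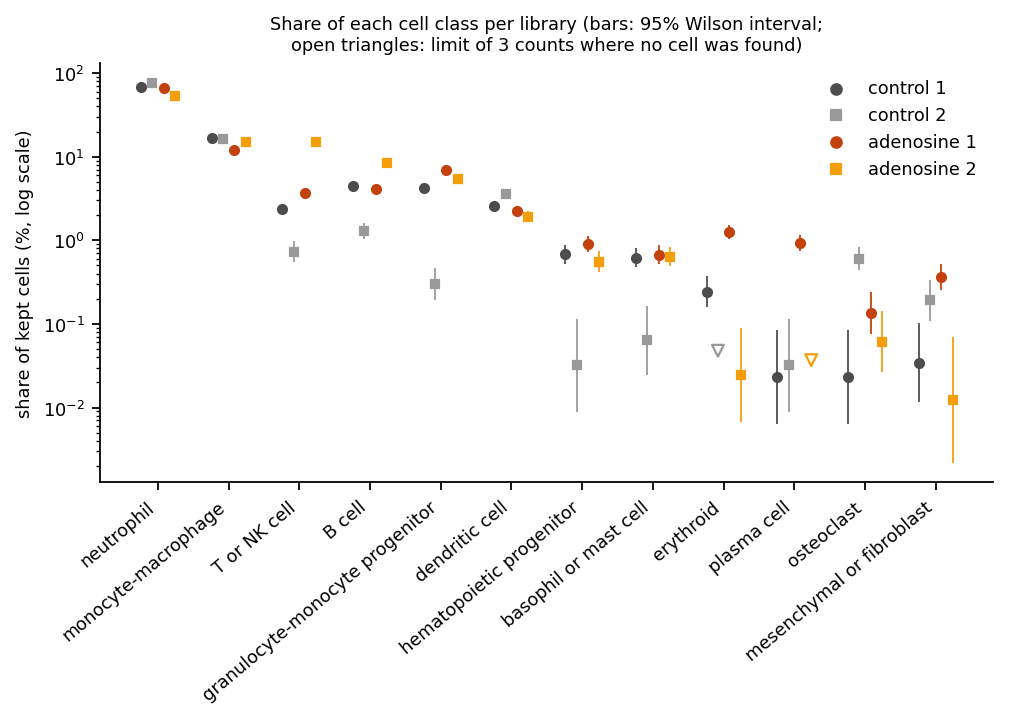
Share of kept cells in each named cell class, per library, on a log scale. Bars are 95% Wilson intervals, and open triangles mark the limit of 3 counts where no cell of a class was found.

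In the counts summed over all cells, inflammatory mediators and genes of mature neutrophils were lower, and cell cycle and primary granule genes higher, in the adenosine libraries by camera at its preset correlation, but control 2 carried much of each difference. These calls were lost with the correlation between genes estimated from the data (adjusted p 0.683 to 0.711 for all 17 called lists). Il1b, the cytokine interleukin-1 beta, stood at 234.7, 3147.5, 161 and 116 CPM, and Cxcl3, a neutrophil-attracting chemokine, at 22.1, 514, 13.3 and 1.81. The DNA replication gene Mcm6 stood at 48.2, 11.1, 77.5 and 71.6 CPM, and Elane, the neutrophil elastase of primary granules, at 551, 20.4, 959 and 776. Sums over all cells mix the shares of the cell classes with expression within them. Granulocyte-monocyte progenitors, which carry Elane, made up 4.24%, 0.302%, 6.92% and 5.47% of cells. Ccl6, a chemokine of the mature neutrophil list, was close within each group, at 1010.4, 1035.8, 538 and 481 CPM (log2 -1.19).

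By edgeR, 0 of 16397 genes changed in all cells, with 405 at an unadjusted p under 0.05 and a smallest adjusted p of 0.885; DESeq2 called 18 (6 higher and 12 lower in adenosine), and edgeR with no filter on low counts 0. The lowest unadjusted p-values among the lower genes were those of the dendritic cell lectin Cd209a (22.2, 32.9, 9.15 and 8.87 CPM, log2 -1.82), the iron carrier transferrin, Trf (74.9, 107, 37.8 and 26.9, -1.71), the chemokine Ccl24 (7.87, 61.5, 1.21 and 0.792, -5.40) and Grk5, a kinase of G protein-coupled receptors (241, 276, 146 and 103, -1.26). Among the higher genes with low p-values were the noncoding RNA Pvt1 (25.3, 17.7, 48.1 and 111 CPM, log2 1.76), the repair gene Rdm1 (36.5, 14.3, 76.2 and 79.6, 1.49) and Sytl2, a vesicle transport gene (4.63, 1.60, 9.76 and 31.6, 2.64). All 7 had an adjusted p of 0.885. The 2 groups did not overlap in 35.7% of genes, against 33.3% by chance. The biological coefficient of variation was 0.494, and no count of called genes by edgeR differed from 0 when any 1 library was left out.

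Of the 24 gene lists tested in all cells, camera with its preset correlation called 5 higher and 12 lower in adenosine, and 0 with an estimated correlation, while no single member of any list passed the test over all genes or over its list alone. The inflammatory list was lower (median log2 -2.47, adjusted p = 4.79e-07), with 0 of 23 members higher, and its summed CPM were 765, 16869.8, 656 and 810.3. Also lower were the mature neutrophil list (-1.29, 4.38e-10), alternative macrophage activation, with the lectin Clec10a at 23.4, 28.2, 14.6 and 13.3 CPM (-1.47, 9.45e-06), and hypoxia and glycolysis, with the lactate exporter Slc16a3 at 94.4, 482, 65.2 and 39.3 CPM (-0.9993, 5.37e-05). The interferon response (-0.48, 0.00263), the osteoclast list (-1.52, 0.00263), the cAMP response (-0.66, 0.00735), the dissociation and stress response (-0.87, 0.00775), MHC class II presentation (-0.89, 0.00775), cartilage (-1.62, 0.0216), extracellular matrix and fibrosis (-0.72, 0.0298) and senescence (-0.79, 0.0445) were the other lower lists. Higher were the cell cycle list, with 34 of 34 members higher (0.97, 2.24e-10), ribosomal proteins (0.29, 0.000118), the primary granules (1.47, 0.00263), hemoglobin and erythroid genes (2.17, 0.0180) and mitochondrially encoded genes (0.34, 0.0381). By fry, 0 lists were called. Without control 2, the medians of the lower lists, in the order given, were -0.29, -0.50, -0.22, 0.20, 0.20, 0.08, -0.23, 0.07, -0.09, 1.11, 1.70 and 0.31, and those of the higher lists 0.27, 0.24, 0.57, 1.31 and 0.09. Of the 17 calls 11 then ended, among them the inflammatory list (adjusted p = 0.446), and the extracellular matrix list was called higher (adjusted p = 0.0242). The hemoglobin list rested on adenosine 1, with summed CPM of 192, 19.7, 1883 and 38.8 and 13 of 14 members highest there; without that library its call ended (median -2.61, adjusted p = 0.157). Without adenosine 1, MHC class II presentation (-0.40, 0.636) and mitochondrially encoded genes (0.147) also ended, and the interferon list was called in the other direction (adjusted p = 0.0452, median -0.0927). Without adenosine 2, ribosomal proteins (0.09, 0.532), extracellular matrix (-0.36, 0.586), cartilage, osteoclast, the cAMP response, senescence and mitochondrially encoded genes ended, and without control 1 mitochondrially encoded genes (0.0615). Without control 1, 12 medians grew by over 1.5 times, among them inflammatory mediators (-3.91) and cell cycle (2.23). Calls of 4 lists held whichever library was left out: cell cycle, primary granules, mature neutrophil and alternative macrophage activation.

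Not past the threshold in all cells were the adenosine receptors and handling list (median log2 0.00, adjusted p = 0.623), osteoblast and mineralization (-0.46, 0.0971), angiogenesis and endothelium (-0.41, 0.152), nuclear oxidative phosphorylation genes (0.10, 0.420), secondary and tertiary granules (0.05, 0.772), B lymphopoiesis (0.24, 0.155) and skeletal muscle (-0.11, 0.198). Spp1, the osteopontin gene of the osteoblast list, stood at 59.04, 2932, 143 and 46.9 CPM. Scaled by library size alone, the median of all genes moved from 0.06 to 0.23.

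**Figure D2:**
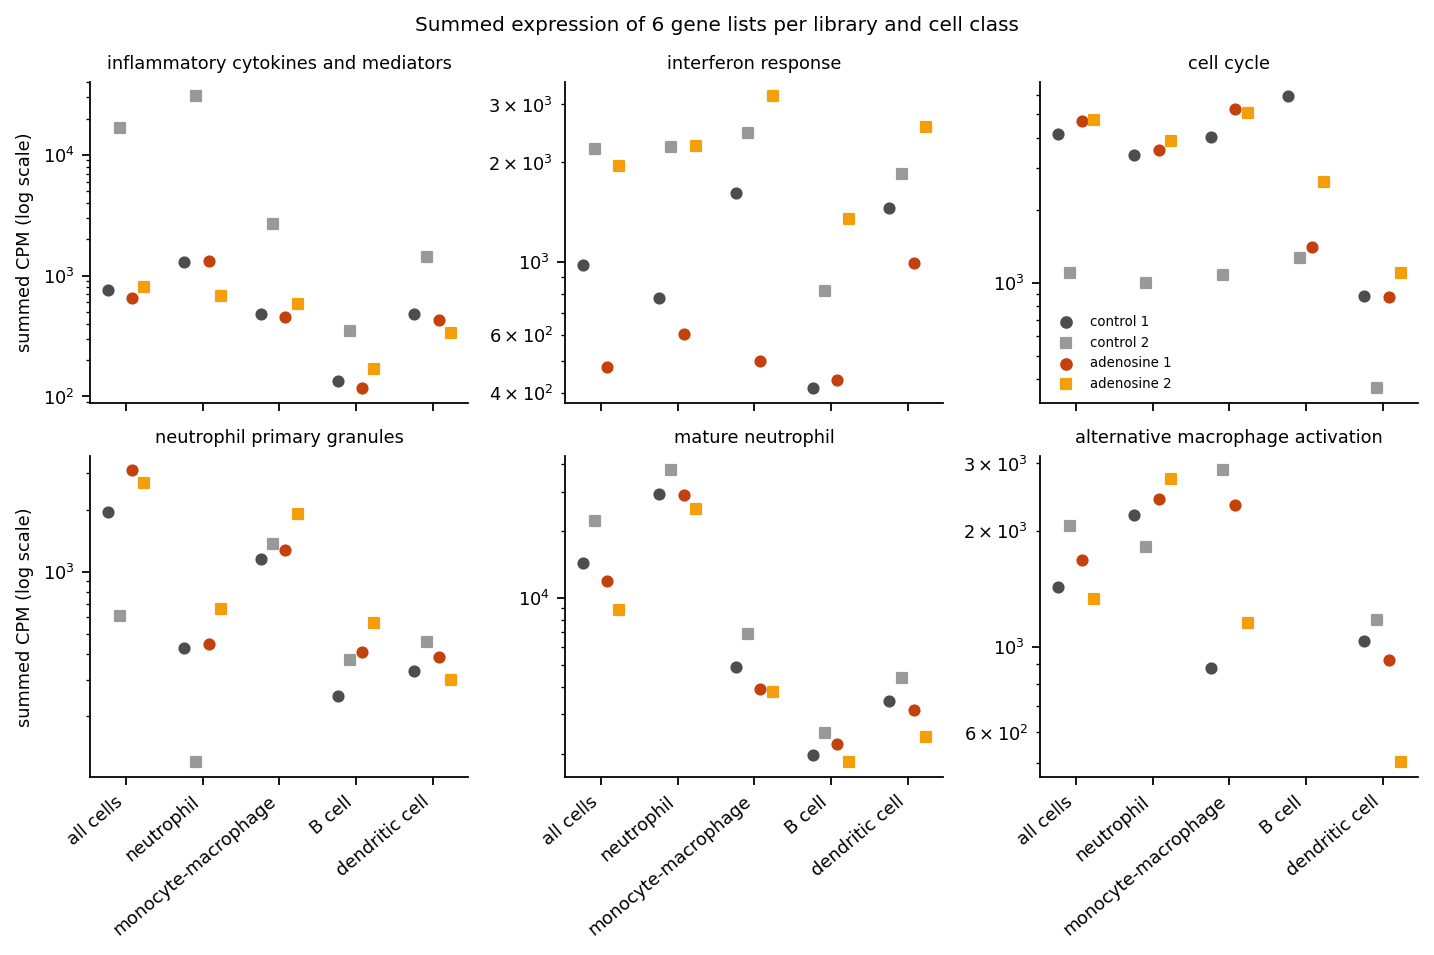
Summed expression of 6 gene lists in CPM (log scale), per library, in all cells and in the 4 tested classes. A class without points had fewer than 5 tested members of that list.

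Within neutrophils, the same lists set control 2 apart: its neutrophils held the most RNA of all 19 tested inflammatory mediators and the least of all 34 cell cycle genes. Il1b stood at 485, 5564, 400 and 323 CPM and Csf1, a growth factor of macrophages, at 29.2, 924, 33.9 and 11.6. Chil3, a secreted chitinase-like protein of granulocyte precursors, ran the other way, at 2069.6, 258, 2296 and 2636 CPM. It is also a member of the alternative macrophage activation list. The guanylate-binding protein Gbp2, induced by interferon, stood at 8.45, 26.4, 41.6 and 187 CPM.

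By edgeR, 0 of 11997 genes changed in neutrophils, with 283 at an unadjusted p under 0.05 and a smallest adjusted p of 0.863; DESeq2 called 47 (3 higher and 44 lower), and edgeR with no filter on low counts 598 (41 higher and 557 lower). The lower genes with the lowest p were Prok2, a chemokine-like prokineticin (25.2, 28.9, 11.2 and 8.56 CPM, log2 -1.64), the magnesium transporter Cnnm2 (32.9, 59.7, 11.0 and 2.67, -3.05), the matrix protein thrombospondin-1, Thbs1 (282, 1642, 104 and 34.1, -4.13), and the cAMP phosphodiesterase Pde7b (99.9, 246, 53.3 and 21.2, -2.50). The higher genes were Jchain, the joining chain of secreted antibodies (6.38, 1.32, 39.1 and 14.4 CPM, log2 2.66; 4.44, 1.11, 22.9 and 6.37 CPM in monocyte-macrophages and 8.20, 1.26, 17.3 and 10.4 in dendritic cells), Gbp2 (2.56), and the class I histocompatibility genes H2-Q6 (2.35, 1.19, 2.21 and 130, 5.21) and H2-Q7 (7.49, 5.83, 5.26 and 242, 4.19). H2-Q6 and H2-Q7 were high in adenosine 2 and not in adenosine 1, and without adenosine 2 the log2 ratio of H2-Q7 was -0.60. The groups did not overlap in 26.0% of genes, against 33.3% by chance, and the coefficient of variation was 0.465. Leaving out control 1 gave 4773 called genes and leaving out control 2 gave 2, in fits that assume the lone control library to vary like the other group; without either adenosine library the count was 0.

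Camera called 7 lists higher and 8 lower in neutrophils out of 23, and all 15 calls were lost with an estimated correlation (adjusted p 0.613 to 0.701). Lower were inflammatory mediators (median log2 -2.85, adjusted p = 2.30e-07), mature neutrophil genes such as the lectin Clec4d (429, 3697, 285 and 215 CPM; list -1.003, 7.63e-06), alternative macrophage activation (-1.42, 6.58e-05), hypoxia and glycolysis (-1.33, 7.13e-05), the dissociation and stress response (-1.06, 0.00229), the cAMP response (-0.80, 0.00254), MHC class II presentation (-0.79, 0.00442) and extracellular matrix (-1.003, 0.00834). Higher were cell cycle (0.97, 3.11e-11), ribosomal proteins (0.33, 0.000206), primary granules (1.35, 0.00287), secondary and tertiary granules (0.53, 0.00365), mitochondrially encoded genes (0.35, 0.00989), hemoglobin (1.49, 0.0254) and oxidative phosphorylation (0.29, 0.0260). No member passed by itself, over all genes or over its list alone. Of 12 tested members of alternative macrophage activation 1 was higher in adenosine. The summed CPM of that list, which includes Chil3, were 2205, 1812, 2427 and 2734, so the sum was not lower in adenosine. The interferon response was not called (-0.000531, adjusted p = 0.501; summed CPM 778, 2235, 602 and 2250). By fry, 0 lists were called. Without control 2, the medians of the lower lists, in the order given, were -0.29, -0.16, -0.87, 0.19, 0.10, -0.17, -0.45 and -0.61, and those of the higher lists 0.23, 0.20, 0.48, 0.03, 0.05, 0.81 and 0.05. Of the 15 calls 5 then ended (the dissociation response, secondary and tertiary granules, mitochondrially encoded genes, hemoglobin and oxidative phosphorylation), and hypoxia and glycolysis was called higher (adjusted p = 0.0326). Without adenosine 1, hemoglobin (-0.43, 0.909) and MHC class II presentation (-0.29, 0.411) ended. Without adenosine 2, ribosomal proteins (0.16, 0.174), oxidative phosphorylation (0.00, 0.685), extracellular matrix (0.240) and mitochondrially encoded genes (0.0610) ended and the primary granule median was 0.86. Without control 1, MHC class II presentation (0.0569) and extracellular matrix (0.0919) ended, and 11 medians grew by over 1.5 times, among them cell cycle (2.53). Clusters 0, 3 and 1 held 61.4% of the neutrophils of control 1 and 60.2% of those of adenosine 1, clusters 6 and 8 held 66.9% of those of control 2, and clusters 5 and 2 held 53.0% of those of adenosine 2. Scaled by library size alone, the median of all neutrophil genes moved from 0.02 to 0.17.

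Monocyte-macrophages of the adenosine libraries held more cell cycle RNA than those of the controls, as a list by camera at its preset correlation. This call was lost with an estimated correlation (adjusted p = 0.858). All 34 cell cycle genes were lowest in control 2, and 31 were higher in both adenosine libraries than in both controls. By chance 33.3% of single genes separate in either direction, but this cannot weigh the count of 31. The estimated correlation between the genes of this list was 0.968, so they are not independent. The mitotic kinase Aurka stood at 24.4, 7.04, 41.1 and 38.4 CPM and the spindle gene Nusap1 at 86.6, 25.7, 139 and 121. Trf, the gene of transferrin, stood at 138, 134, 49.7 and 53.7 CPM and the transcription repressor Bach2 at 81.9, 85.9, 37.7 and 31.4. Chil3 stood at 457, 203, 1643 and 808 CPM.

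By edgeR, 0 of 12530 genes changed in monocyte-macrophages, with 200 at an unadjusted p under 0.05 and a smallest adjusted p of 1.00; DESeq2 called 3 (1 higher and 2 lower), and edgeR with no filter on low counts 225 (37 higher and 188 lower). The lower genes with the lowest p were Trf (log2 -1.49), Bach2 (-1.39), the protease inhibitor Stfa2l1 (17.1, 27.0, 7.19 and 4.99 CPM, -1.99; 668, 1569, 983 and 636 in neutrophils) and Ccl24 (24.4, 176, 4.36 and 2.43, -5.07). The higher genes were Chil3 (log2 1.80), the leucine-rich repeat gene Lrrc20 (13.3, 12.4, 30.6 and 22.9, 0.95), the growth factor neuregulin-1, Nrg1 (84.7, 46.6, 172 and 124, 1.08), and Prrg1, a vitamin K-dependent membrane protein (9.94, 4.22, 17.8 and 23.1, 1.47). The groups did not overlap in 24.4% of genes, against 33.3% by chance, and the coefficient of variation was 0.358. The share of neutrophil RNA in this class was not estimated. Without control 1, edgeR called 608 genes, and without control 2, 1; without either adenosine library it called 0.

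Of 23 lists in monocyte-macrophages, camera called 2 higher and 7 lower, and all 9 calls were lost with an estimated correlation (adjusted p 0.858). Cell cycle (median log2 1.06, adjusted p = 5.70e-21) and primary granules (0.83, 0.000845) were higher, and the cAMP response (-0.67, 0.000843), mature neutrophil genes (-0.63, 0.000843), the interferon response (-0.44, 0.00121), alternative macrophage activation (-1.05, 0.00214), hypoxia and glycolysis (-0.77, 0.00342), inflammatory mediators (-1.90, 0.00415) and the osteoclast list (-1.08, 0.0382) lower. Of 17 tested members of alternative macrophage activation, a list that includes Chil3, 2 were higher in adenosine. The summed CPM of that list were 882, 2873, 2333 and 1152, with control 1 below both adenosine libraries. Interferon genes differed within the groups, with summed CPM of 1619, 2450, 500.1 and 3174, and 29 of 31 members lowest in adenosine 1. No member passed by itself, over all genes or over its list alone. By fry, 0 lists were called. Without control 2, the medians in the order given were 0.48 and 0.16 for the higher and -0.19, -0.12, -0.07, 0.16, 0.27, 0.32 and 0.06 for the lower lists. Of the 9 calls 5 then ended (primary granules, mature neutrophil genes, alternative activation, inflammatory mediators and osteoclast), and hypoxia and glycolysis was called higher (adjusted p = 0.00125). Without adenosine 1, the inflammatory call ended (adjusted p = 0.0539) and the interferon list was called higher (median 0.28, adjusted p = 4.98e-05); without adenosine 2, alternative activation (0.249), osteoclast (0.398), the cAMP response and hypoxia (0.0551 each) ended. Without control 1, 7 medians grew by over 1.5 times, among them cell cycle (2.16). Only the cell cycle call held whichever library was left out. Cluster 7 held 56.8% of the class in control 1 and 58.8% in adenosine 1, cluster 9 held 84.5% in control 2, and cluster 13 held 55.2% in adenosine 2. Cluster 15, whose next best name was granulocyte-monocyte progenitor, held 13.9%, 1.64%, 20.6% and 22.8%.

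B cells of control 1 held the most RNA of all 34 cell cycle genes and of 12 of the 20 genes of the B lymphopoiesis list, of which 4 were highest in control 2 and 4 in adenosine 1. Camera called neither list (median log2 -0.94, adjusted p = 0.0734 for cell cycle and -0.25, 0.0824 for B lymphopoiesis). Vpreb1 and Igll1, which form the surrogate light chain of B cell precursors, stood at 802, 373, 116 and 179 CPM and at 648, 290, 95.8 and 146. Enpep, an aminopeptidase of early B cells, stood at 85.7, 29.8, 4.41 and 3.99 CPM, and the cytokine signaling inhibitor Socs2 at 72.0, 48.7, 12.6 and 8.32.

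By edgeR, 0 of 10244 genes changed in B cells, with 407 at an unadjusted p under 0.05 and a smallest adjusted p of 0.814; DESeq2 called 5, all lower, and edgeR with no filter on low counts 82 (25 higher and 57 lower). The lower genes with the lowest p were Enpep (log2 -3.87, adjusted p = 0.814), Socs2 (-2.61), Crhbp, which binds corticotropin-releasing hormone (70, 6, 3 and 7 UMIs, -3.41), and the detoxifying enzyme Gstp1 (84.5, 70.4, 17.6 and 21.97 CPM, -1.98). The higher genes were the calcium-binding S100a4 (38, 1, 222 and 100 UMIs, log2 2.82), the immediate-early gene Fosb (10.5, 13.5, 32.1 and 35.6 CPM, 1.58), the membrane transporter Sidt1 (34.6, 32.5, 64.9 and 92.2, 1.22) and the surface receptor Slamf1 (12.1, 13.5, 29.6 and 39.9, 1.49). Control 2 held only 81 B cells. The groups did not overlap in 31.4% of genes, against 33.3% by chance, and the coefficient of variation was 0.285. Without control 1, 23 genes were called, without control 2, 26, without adenosine 1, 19, and without adenosine 2, 9.

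The adenosine list was not called in B cells, with 8 of 14 members higher (median log2 0.11, adjusted p = 0.541). Adjusted over the list alone, 3 of its members fell: the hydrolase Ahcy (31, 6, 2 and 5 UMIs, log2 -3.13), the adenosine transporter Slc29a1 (51.5, 21.7, 10.1 and 7.32 CPM, -2.21) and the nucleoside phosphorylase Pnp (175, 94.7, 48.5 and 68.6 CPM, -1.24). On the same footing 2 members of the B lymphopoiesis list fell, Vpreb1 (-1.99) and Igll1 (-1.96), and 1 each of the inflammatory and mature neutrophil lists, in both Il1b (39, 47, 3 and 10 UMIs, -4.54). Neutrophils of control 2 held 5564 CPM of Il1b, against 127 in its B cells. Of 17 lists, camera called 5, all lost with an estimated correlation (adjusted p 0.617 to 0.742): nuclear oxidative phosphorylation (median log2 -0.53, adjusted p = 5.17e-10; Ndufa4 at 437, 379, 187 and 269 CPM), ribosomal proteins (-0.39, 8.79e-05), hypoxia and glycolysis (-0.55, 0.00215) and mature neutrophil genes (-0.42, 0.0110) lower and primary granules (0.82, 0.00196) higher. The cell cycle list, at summed CPM of 5948, 1264, 1403 and 2625, was not called (-0.94, 0.0734). By fry, 0 lists were called. Without control 2, ribosomal proteins (median 0.06, adjusted p = 0.368), hypoxia and glycolysis (-0.41, 0.147) and mature neutrophil genes (-0.38, 0.201) ended. Without adenosine 2, hypoxia (-0.24, 0.0591) and mature neutrophil genes (-0.53, 0.0858) ended. Without adenosine 1, ribosomal proteins ended (-0.12, 0.245) and the oxidative phosphorylation median was -0.30. Without control 1, the primary granule median was 6.77 and the ribosomal median -0.73. The primary granule value rests on the 81 B cells of control 2 as the lone control. Summed CPM of that list, at 251, 373, 410 and 566, did not show a difference of this size. Cluster 10 held 61.4%, 82.7%, 72.2% and 84.7% of the B cells, and cluster 22, with Vpreb1, Vpreb3 and Igll1 among its top genes, 29.5%, 11.1%, 11.4% and 13.1%.

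In dendritic cells of the adenosine libraries the inflammatory list was lower and the cell cycle list higher than in those of the controls, by camera at its preset correlation. Both calls were lost with an estimated correlation (adjusted p 0.415). Thbs1 was found with 75, 152, 3 and 1 UMIs (log2 -5.64), and the transcription factor Cebpb stood at 108, 267, 47.5 and 43.7 CPM (-2.20). The mature neutrophil list was lower in this class too (median log2 -1.09), and Thbs1 stood at 282, 1642, 104 and 34.1 CPM in neutrophils. The share of neutrophil RNA in this class was not estimated. The DNA topoisomerase of dividing cells, Top2a, stood at 19.4, 2.94, 41.3 and 42.6 CPM. H2-Ab1, a class II antigen-presenting molecule, stood at 3844, 6082, 3595 and 2818 CPM.

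By edgeR, 0 of 10440 genes changed in dendritic cells, with 203 at an unadjusted p under 0.05; Thbs1 had the smallest adjusted p, 0.414, DESeq2 called 2 (1 higher and 1 lower), and edgeR with no filter on low counts 79 (24 higher and 55 lower). The other lower genes with the lowest p were Cebpb, the lipolysis inhibitor G0s2 (12.1, 34.9, 4.80 and 2.18 CPM, log2 -2.88) and the survival gene Bcl2a1a (25.9, 46.2, 12.5 and 6.55, -2.06). The higher genes were Cdh5, a cadherin of endothelium (9.93, 6.31, 22.5 and 30.01 CPM, log2 1.58), the RNA-binding gene Arpp21 (9.06, 1.68, 22.1 and 37.1, 2.37, but -0.0645 without doublet removal), the Rab exchange factor Dennd5b (13.4, 6.31, 26.4 and 38.2, 1.61) and the chondroitin synthase Chsy3 (22.4, 7.57, 101 and 34.4, 2.07). The groups did not overlap in 24.9% of genes, against 33.3% by chance, and the coefficient of variation was 0.3302. Without control 1, 276 genes were called, without control 2, 2, and without either adenosine library, 1.

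Of 19 lists in dendritic cells, camera called 3 higher and 11 lower, and all 14 calls were lost with an estimated correlation (adjusted p 0.415 to 0.719). Higher were cell cycle (median log2 0.89, adjusted p = 2.69e-13), B lymphopoiesis, with the polymerase Dntt at 27.2, 26.1, 53.3 and 62.2 CPM (0.86, 0.000227), and angiogenesis and endothelium (0.42, 0.0223). Lower were mature neutrophil genes (-1.09, 1.10e-08), ribosomal proteins (-0.26, 3.12e-05), oxidative phosphorylation (-0.30, 0.000181), alternative macrophage activation (-0.88, 0.000227), the cAMP response (-0.33, 0.000238), MHC class II presentation (-0.68, 0.000428), inflammatory mediators (-0.81, 0.000769), the dissociation and stress response (-0.34, 0.00227), hypoxia and glycolysis (-0.55, 0.00271), senescence (-0.47, 0.00271) and the interferon response (-0.27, 0.0248). Adjusted over the list alone, Thbs1 fell within the cAMP response and Cxcr2, the neutrophil chemokine receptor (40, 38, 9 and 5 UMIs, -2.33), within the mature neutrophil list. By fry, 0 lists were called. Without control 2, the medians in the order given were 0.34, 0.37 and 0.50 for the higher and -0.53, -0.10, 0.01, -0.29, -0.40, -0.06, -0.37, -0.08, 0.25, -0.09 and 0.33 for the lower lists. Of the 14 calls 7 then ended (angiogenesis, ribosomal proteins, oxidative phosphorylation, MHC class II presentation, dissociation, senescence and interferon), and hypoxia and glycolysis was called higher (adjusted p = 0.0177). Without adenosine 1, angiogenesis (0.135), oxidative phosphorylation (median -0.14, 0.314) and ribosomal proteins (-0.14, 0.164) ended and the interferon list was called in the other direction (adjusted p = 0.0471, median -0.13); without adenosine 2, the cAMP response (-0.07, 0.520), alternative activation (0.789) and senescence (0.0721) ended and the cell cycle median was 0.59. Without control 1, angiogenesis ended (0.0878) and 12 medians grew by over 1.5 times, among them cell cycle (1.88) and inflammatory mediators (-1.77). Calls of 4 lists held whichever library was left out: cell cycle, B lymphopoiesis, inflammatory mediators and mature neutrophil genes. Cluster 18 held 63.3%, 75.1%, 63.0% and 50% of the dendritic cells, and cluster 25, with the plasmacytoid genes Siglech and Tcf4 among its top genes, 23.98%, 6.67%, 19.0% and 42.9%. Scaled by library size alone, the median of all dendritic cell genes moved from -0.01 to 0.11.

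Of the adenosine receptors, Adora2b, which couples to cAMP, was found mainly in monocyte-macrophages, at 24.4, 40.3, 22.8 and 23.1 CPM (369, 401, 266 and 351 UMIs, against 451, 500, 355 and 427 in all cells). Adora2a stood at 4.35, 3.85, 3.43 and 11.98 CPM in all cells (log2 0.78); of the 696 UMIs in adenosine 2, 555 were in T or NK cells, which held 53.1, 32.1, 39.7 and 44.1 CPM. Adora3 stood at 2.20, 7.13, 2.99 and 2.00 CPM (-1.16), and Adora1 had 0 UMIs in every library. Nt5e, which makes adenosine from AMP outside the cell, stood at 19.3, 58.0, 15.3 and 11.3 CPM in all cells (-1.79) and at 4.31, 86.3, 4.19 and 1.12 in monocyte-macrophages (-4.32). Entpd1, which makes AMP from ATP outside the cell, stood at 153, 563, 125 and 124 CPM in all cells (-1.77) and at 284, 1017, 265 and 226 in neutrophils (-1.67). Control 2 carried most of these ratios of Nt5e and Entpd1, since control 1 lay far nearer to the adenosine libraries. The adenosine-clearing enzymes Ada (8.27, 2.11, 8.76 and 8.40 CPM, 0.61) and Adk (79.1, 22.9, 108 and 61.1, 0.60) were lowest in control 2. Without adenosine 2 the log2 ratio of Adora2a in all cells was -0.50, and without control 2 those of Adora3 and Ada were 0.0999 and -0.0133. None of the 7 detected genes passed the edgeR test in all cells or in a class where it was tested. In all cells each had an adjusted p of 0.885. The filter on low counts left Adora2a and Adora2b untested in neutrophils and Adora2b and Adora3 untested in B cells. No gene was tested within T or NK cells.

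**Figure D3:**
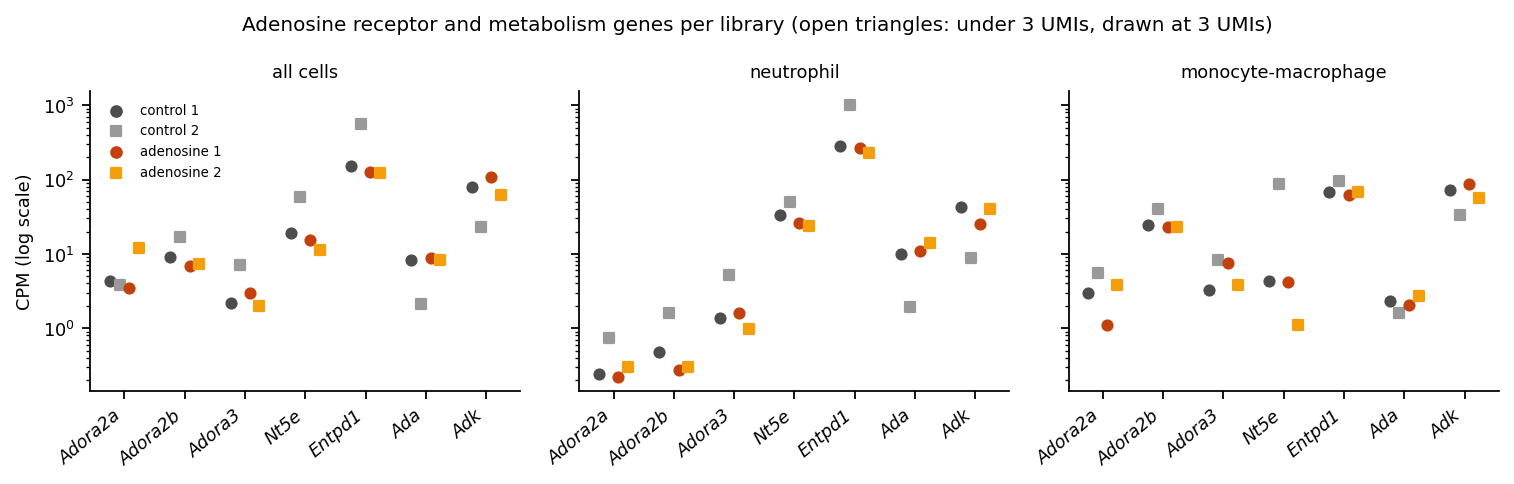
Adenosine receptors and enzymes that make or clear adenosine, in CPM (log scale), per library, in all cells, neutrophils and monocyte-macrophages. Adora1 had no counts and is not drawn.

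The difference of the change between neutrophils and monocyte-macrophages was tested in edgeR with the library as a block. Of 13573 genes, 0 passed, 205 had an unadjusted p under 0.05 and the smallest adjusted p was 0.922; DESeq2 was not run on this term. The cytokine gene Il1a had the lowest p (log2 difference 4.91, adjusted p = 0.922). Without control 1, 3018 genes passed; without any other library the count was 0.

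Gene ranks were closer between some libraries of different groups than within the control group. In neutrophils, where Chil3 stood at 258 CPM in control 2 and at 2069.6 to 2636 in the 3 other libraries, Spearman's rank correlation was 0.881 between the 2 control libraries, 0.975 between the 2 adenosine libraries, 0.989 between control 1 and adenosine 1 and 0.870 between control 2 and adenosine 1. In all cells these values were 0.930, 0.958, 0.982 and 0.918. All libraries held Y-linked transcripts of male mice: Ddx3y stood at 69.6, 99.5, 74.6 and 46.6 CPM, and Xist, from the inactive X chromosome of females, had 2, 0, 5 and 6 UMIs.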

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

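The test on thinned counts was chosen after the data were seen; all other alternatives were planned. Counts of called genes stayed at 0 in all cells and the 4 tested classes with size factors of the DESeq2 type, library size only, stricter cells, no doublet removal, thinned counts and the replicate block (paired by number). Cell classes with a changed number stayed at 0 in all 13 alternatives. DESeq2 called 18 genes in all cells, 47 in neutrophils, 3 in monocyte-macrophages, 5 in B cells and 2 in dendritic cells. With no filter on low counts edgeR called 0 in all cells and 598, 225, 82 and 79 in these 4 classes. The cause was not tested. With 1 library left out the counts ranged from 0 to 4773 in neutrophils, 0 to 608 in monocyte-macrophages, 9 to 26 in B cells, 1 to 276 in dendritic cells and 0 to 3018 for the difference between neutrophils and monocyte-macrophages. The highest came without control 1, except in B cells (26 without control 2). These fits rest on a lone library in 1 group, assumed to vary like the other group.

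Called lists numbered 17, 15, 9, 5 and 14 in all cells, neutrophils, monocyte-macrophages, B cells and dendritic cells, and 0 in each with an estimated correlation and by fry. With the replicate block they numbered 14, 17, 12, 8 and 13. Leaving out 1 library gave 8 to 19 in all cells (8 without control 2, 10 without adenosine 2, 16 without adenosine 1 and 19 without control 1) and 8 to 12 in B cells; neutrophils had 12 to 17, monocyte-macrophages 7 to 13 and dendritic cells 10 to 14. Thinning gave 17, 15, 10, 4 and 14. Over the 60 called lists, 171 of 299 values under other settings kept their call and 128 lost it with the same sign. With 1 library left out 168 of 240 calls were kept, 65 ended and 7 were called in the other direction; 20 medians changed sign.

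List medians that changed sign with control 2 left out ranged over the libraries left out, in all cells, from -1.40 to 0.0665 (dissociation), -1.99 to 0.20 (interferon), -2.35 to 1.11 (cartilage), -2.18 to 0.0772 (osteoclast), -2.41 to 1.70 (extracellular matrix), -1.65 to 0.20 (hypoxia) and -1.55 to 0.31 (senescence). In neutrophils they ranged from -1.71 to 0.0984 (dissociation) and -2.01 to 0.19 (hypoxia); in monocyte-macrophages from -2.88 to 0.32 (inflammatory), -2.45 to 0.16 (alternative activation), -2.015 to 0.0581 (osteoclast) and -1.31 to 0.27 (hypoxia). In B cells the ribosomal median ranged from -0.73 to 0.0578; in dendritic cells the ranges were -1.01 to 0.33 (interferon), -1.0 to 0.25 (hypoxia) and -0.57 to 0.0144 (oxidative phosphorylation). Without adenosine 1, hemoglobin changed sign in all cells (-2.61 to 5.97) and neutrophils (-0.43 to 2.56), and the interferon list in monocyte-macrophages (-2.20 to 0.28).

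Log2 ratios of cell numbers changed sign for erythroid cells (-2.24 to 8.58), mesenchymal cells (-3.02 to 2.40), osteoclasts (-2.61 to 2.017), plasma cells (-4.152 to 5.025) and unnamed cells (-0.65 to 4.07) with 1 library left out. By marker score per cell they were -2.20 for basophils or mast cells, -0.69 for mesenchymal cells and 0.19 for neutrophils; against cells outside the most abundant class unnamed cells had -0.0391. Only 65.6% of cells had the same class by score and by cluster.

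Of 71 named log2 ratios none had passed; under other settings 519 of 559 values stayed so, 33 passed with the same sign and 7 changed sign, and with 1 library left out 225 of 284 stayed so, 34 passed and 25 changed sign. With 1 library left out sign changes were, in all cells, Adora2a (-0.50 to 1.45), Adora3 (-1.87 to 0.0999) and Ada (-0.0133 to 1.68); in neutrophils, H2-Q7 (-0.60 to 5.17) and Adk (-0.37 to 1.61); in monocyte-macrophages, Adora3 (-0.76 to 0.77), Ada (-0.0723 to 0.45) and Adk (-0.00420 to 0.93); in B cells, Adora2a (-0.0184 to 0.80), Nt5e (-1.55 to 2.36), Entpd1 (-0.28 to 0.38), Ada (-2.00 to 0.98) and Adk (-0.44 to 1.475); in dendritic cells, Adora2b (-0.59 to 0.32), Adora3 (-1.25 to 0.65), Nt5e (-6.285 to 0.80), Entpd1 (-0.20 to 0.33) and Adk (-0.16 to 2.10). Without doublet removal, Adora3 in monocyte-macrophages was 0.0142, and in dendritic cells Arpp21 was -0.0645, Adora2a -0.10 and Entpd1 -0.31. With stricter cells, Entpd1 and Adk in B cells were -0.0369 and -0.11; thinned, Adk was -0.22. The cause was not tested.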

Other observations

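Tests chosen after the result was seen were those of the marrow share in control 2 and of a shared treatment effect on interferon genes, and both are left open. For the tests of heat-shock genes and of free immunoglobulin RNA, the rule for calling the outcome was made stricter after the values were seen, which left both open.

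Control 2 differed from control 1 in neutrophils about as much as from adenosine 1: Spearman's rank correlation was 0.881 and 0.870, against 0.989 between control 1 and adenosine 1. Its lower depth did not account for this, since control 1 thinned to the neutrophil total of control 2 kept a correlation of 0.989 (0.9888) with adenosine 1. Dissociation stress cannot be told apart from other causes: heat-shock genes in neutrophils had a median log2 of 0.38 over control 1, under the limit of 0.5 written beforehand, but their quartiles ran from -0.30 to 0.76, and the 13 other members of the list had 2.67 and were all higher. Less bone marrow in the suspension of control 2 cannot be told apart from other causes either. Of 5 classes taken to mark marrow, 4 had a lower share there than in the other 3 libraries beyond counting error. They were granulocyte-monocyte progenitors, hematopoietic progenitors, basophils or mast cells and B cells, and not all of these are precursors. Erythroid cells did not pass. This count was chosen from those shares, and single libraries give no spread. No biological explanation was tested, since both libraries belong to the control group.

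Interferon-response genes were high in adenosine 2 and low in adenosine 1 in several classes. Their summed CPM in monocyte-macrophages were 1619, 2450, 500.1 and 3174 in control 1, control 2, adenosine 1 and adenosine 2. In neutrophils they were 778, 2235, 602 and 2250, so control 2 was about as high there as adenosine 2. In neutrophils of adenosine 2, free RNA from other cells, judged by T or NK cell markers, did not account for the high values. Relative to all cells, neutrophils held 1.16 times the CPM of interferon-response genes at the median. For T or NK cell markers they held 0.0396 times, a ratio of 29.2 between the 2 sets. Other classes were not tested in this way. A treatment effect shared by both adenosine libraries cannot be told apart from differences between single libraries: 4 of 30 tested members were higher in both adenosine than in both control libraries in neutrophils, but the low values of adenosine 1 define the pattern and fix this count. T or NK cells of adenosine 2 held 85.3 CPM of Ifng, the interferon gamma gene, against 20.8, 9.64 and 13.2 in control 1, control 2 and adenosine 1. Control 2, where interferon-response genes were also high, held 3 Ifng UMIs in all cells. Whether interferon gamma from T or NK cells was the cause cannot be told apart from type I interferon, as 6 genes of the gamma type exceeded 12 of type I by a median log2 of only 0.35, at 2.90 and 2.55. The chemokine gene Cxcl9 stood at 31.1, 0, 0.171 and 110 CPM in monocyte-macrophages of control 1, control 2, adenosine 1 and adenosine 2, and so was not high in control 2.

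In neutrophils, RNA of Igkc, the immunoglobulin kappa light chain, stood at 90.3, 36.2, 557 and 141 CPM and that of Jchain at 6.38, 1.32, 39.1 and 14.4, highest in both adenosine libraries, while Ighm, the mu heavy chain, stood at 86.6, 23.0, 216 and 84.6, with adenosine 2 below control 1. Doublets with plasma cells did not account for Igkc in adenosine 1, where the 1% of neutrophils with the most Igkc held 7.29% of its UMIs and 4226 of 5484 neutrophils held at least 1. Free RNA from plasma and B cells may have added Igkc, and this cannot be told apart from other sources: the ratio of Igha to Igkc differed by at most 1.24 times between neutrophils, monocyte-macrophages and dendritic cells of adenosine 1, within the 1.5 times written beforehand, but in neutrophils it was 3.86 times that of its 77 plasma cells. Over all cells Igkc stood at 188, 848, 12470 and 459 CPM, higher in control 2 than in adenosine 2, while neutrophils of control 2 held the least. That sum includes the plasma cells themselves, which numbered 2 in control 2, with 63477 UMIs of all genes, and 0 in adenosine 2. A few cells can thus set the value of control 2. The sort for viable cells, per the labels, names no gate against plasma cells. Igkc was also highest in both adenosine libraries in monocyte-macrophages (64.8, 32.2, 341 and 89.3 CPM) and dendritic cells (69.1, 42.0, 341 and 139). The difference was thus not particular to neutrophils. These values argue against a treatment effect confined to neutrophils as the source. A treatment effect shared by these classes stays open and was not tested.

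T or NK cells of adenosine 2 also differed in their markers, in values chosen after they were seen. Ccl5, a chemokine of effector T and NK cells, stood at 3866, 3456, 3464 and 17734 CPM in control 1, control 2, adenosine 1 and adenosine 2, the coreceptor chain Cd8b1 at 119, 279.5, 108 and 908, and Tcf7, a transcription factor of naive T cells, at 357, 308, 360 and 36.3. Of its 1220 such cells, 769 lay in cluster 14, which held 2, 1 and 0 in the other libraries, 297 in cluster 21 (4, 0 and 12), and 9.10% in cluster 17, which held 77.2%, 82.6% and 72.2% there. Control 2 held 46 of these cells. Plasma cells numbered 2, 2, 77 and 0.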
